A study of Bacillus subtilis with 6 samples.

How the data were processed

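Transcript abundance was measured by RNA sequencing in *Bacillus subtilis* RNC-6, a strain of a rod-shaped, spore-forming soil bacterium. Per the labels, 6 libraries fall into 3 groups of 2, namely a control, growth overnight at pH 4.0 and growth overnight at pH 5.0. The labels do not give the pH of the control. They describe the molecule as polyA RNA and the libraries as made with a Qiagen mRNA kit, and they do not say whether the libraries of a group came from separate cultures.

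The authors deposited a table of estimated counts per transcript that were not normalised. Per the submitters' processing notes, the tools were FastQC, Trim Galore and kallisto, a pseudoaligner that shares ambiguous reads among transcripts. Their versions, the transcript set, the genome build and the way transcripts were paired with genes are not given in the sources used here. The table held 54234 rows, each with a UniProt identifier and most with a gene name and product, and 370 rows had no gene name. A gene was spread over several rows, up to 134 for a single name, so rows of the same name were summed before analysis. That gave 9607 genes, of which 3204 carried a symbol or synonym found in a reference gene table of the species, which was used for names and for which genes neighbour each other. The reference lists 4237 protein-coding genes, so the 9607 cannot all be distinct genes of it. Genes below therefore means summed gene names. Reads of near-identical genes could be split between rows by the counting, and strand was not stated, so paralogs and overlapping genes are uncertain. No row carried the product of a ribosomal or other stable RNA, and no column of per-sample values was left unused.

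Library totals ranged from 8091742 to 10048696 estimated counts. At that depth a count of 0 was treated as an upper limit of 3 counts in a library of the group's mean size, and a gene at 0 in a group is given as at least N-fold higher or lower against that floor. Estimated counts were rounded to whole numbers after summing. Values are counts per 1000000 (CPM) of library totals scaled by TMM factors, which lay between 0.940 and 1.07. Folds are ratios of mean CPM. Their 95% intervals are exact Clopper-Pearson intervals on the mean counts of the groups and cover counting error only, since reads without molecular identifiers are not independent molecules.

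Replicates were compared before averaging. In rows that held at least 200 counts per pair and whose replicates lay within 0.05 on the log2 scale of the pair's common ratio in the other groups, the median squared difference of replicate counts was far below that of counting noise. Even so, 146 of 1935 such rows in the control, 214 of 1968 at pH 4.0 and 71 of 1852 at pH 5.0 lay 2-fold or more apart. A row is called closely matching where more of its pairs lay within 0.05 of the common ratio than outside it. Pairs under 200 counts, or 2-fold or more from that ratio, were left out of this tally. There were 3518 closely matching rows, against 6367 other rows and 44349 rows without a pair that could be judged. The libraries of a group were therefore counted as 1 sample, so n = 1 per group, no comparison has a replicate check and no p-value per gene is given. In their place genes are described by a rule of size, under which CPM + 1 had to lie at least 2-fold apart in all 4 pairings of libraries. The size rule, the row classes, the random-list percentiles and the choice of which gene lists to describe were made after the data were seen. For each gene, the share of its counts over all libraries that came from closely matching rows was recorded.

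The test fixed before the data were examined was edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at a threshold of 0.05, two-sided, with all 3 groups in a single fit, TMM scaling, the filterByExpr filter and no block. It left 8769 genes, 3126 of them found in the reference table. Its counts are given per comparison and per list described. They, and the p-values of the list tests, rest on the spread between library files that are not independent, so they carry no replicate check. Before the data were examined, 38 gene lists were fixed, of which 37 had at least 5 measured members. They were tested with camera (limma) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, with an estimated correlation and with fry beside it. The median log2 ratio of CPM + 1 of each list was also placed among 10000 random lists of the same size, drawn from reference genes in 20 bins of expression. The random lists were not matched for the share of closely matching rows. Percentiles are relative to reference genes, of which more were higher than lower against the control by the size rule (854 and 558 at pH 4.0, 825 and 337 at pH 5.0). A floor-based median uses the floor of 3 counts in place of the added 1 CPM and leaves out members at or under the floor in both groups. Under chance alone 1.85 of 37 lists would lie outside the middle 95%.

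Genes are named by a rule fixed before the data were examined. It takes the 5 largest differences in each direction among symbol-bearing genes past the edgeR threshold with at least 10 counts in the higher group and no overlap between groups. It adds up to 4 members of each list past camera, up to 2 of each other list described, by smallest edgeR p, and 16 genes fixed in advance, of which 14 were measured. The fixed genes *gsiB* and *ctc* had 0 rows.

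The scripts were tested on simulated counts with 200 changed genes per comparison. Changed genes were drawn from those with at least 50 counts. Among 100 genes changed 4-fold, edgeR recovered 26, 35 and 45 for pH 4.0 against control, pH 5.0 against control and pH 4.0 against pH 5.0, and the size rule recovered 90, 85 and 95. Among 100 changed 2-fold, edgeR recovered 2, 1 and 1 and the size rule 13, 14 and 13. Of 8769 genes, the unchanged ones called numbered 1, 5 and 1 by edgeR and 60, 65 and 79 by the size rule. The simulated libraries were drawn independently, unlike the closely matching rows, so these rates need not hold for the deposited counts. On independent Poisson counts the statistic of replicate differences gave 0.99 times counting noise.

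Alternatives covered the scaling (RLE, library totals alone, upper quartile), the filter on low counts, DESeq2 and limma-voom, fits of only the groups compared, a replicate block, rows as deposited, a 2-fold limit beside the adjusted p, each library left out in turn, reference genes only, and closely matching or other rows only. Unchanged groups were simulated in 20 draws for the comparisons that share the control. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.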

Results

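RNA was sequenced from *B. subtilis* RNC-6 after overnight growth at pH 4.0 or pH 5.0 and from controls whose pH the labels do not give, with 2 libraries in each of the 3 groups. The control libraries held 10048696 and 8863140 estimated counts, the pH 4.0 libraries 8091742 and 8153858, and the pH 5.0 libraries 9270463 and 8417430. The 10 most abundant genes took 15.9% and 16.4% of the counts in the control libraries, 3.74% and 3.63% at pH 4.0, and 4.39% and 4.61% at pH 5.0.

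In part of their rows, the replicate libraries were not independent of each other. In rows picked because their replicates lay close together in the other groups, the median squared difference between replicates was 0.037 of that of counting noise in the control, 0.024 at pH 4.0 and 0.035 at pH 5.0. Of these rows, 146 of 1935, 214 of 1968 and 71 of 1852 lay 2-fold or more apart between replicates. Rows picked because their replicates differed gave 1.82, 1.5 and 1.77 times counting noise. The closely matching rows carried between 45.1% and 56.5% of the counts of a library. Across rows, levels in the closely matching rows had a Spearman rho of 0.17 to 0.21 between groups, against 0.59 to 0.80 in the other rows. Between 25 and 134 rows per library held at most 10 counts where the replicate held at least 1000. Across 2214 pairs of neighbouring genes, which are not independent replicates, log2 folds against the control had a Pearson r of −0.015 at pH 4.0 and 0.028 at pH 5.0. Since the median squared difference in the rows picked for close replicates was below that of sampling noise, each group was counted as 1 sample. All values describe these libraries with no replicate check. Intervals are 95% exact intervals and cover counting error only.

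**Figure D1:**
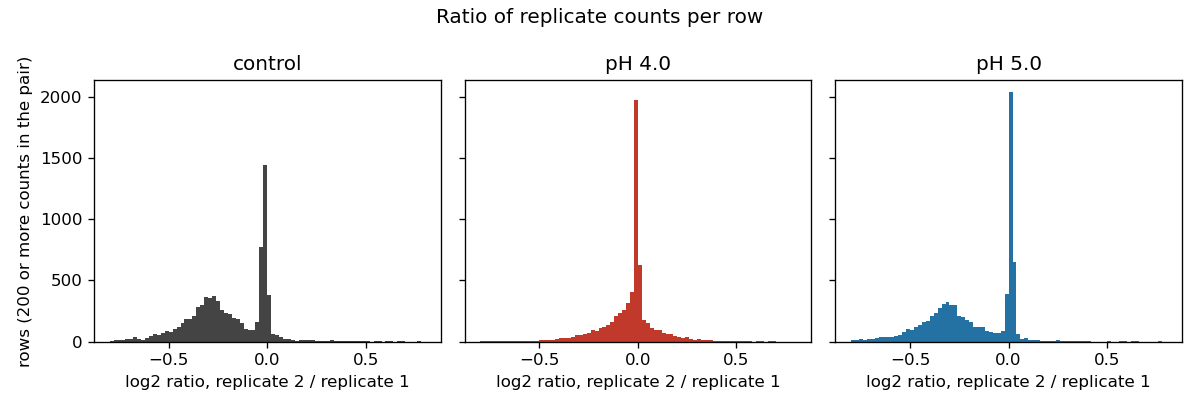
Histograms of the log2 ratio of replicate 2 to replicate 1 (horizontal axis) for rows with 200 or more counts in the pair, with the number of rows on the vertical axis, 1 panel per group. Each panel has a narrow peak near 0, where closely matching rows lie, beside a broad spread of other rows. Rows picked for close replicates in the other groups had a median squared difference of 0.024 to 0.037 of that of counting noise.

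The first comparison asked which transcripts differed between overnight growth at pH 4.0 and the control. Flagellin (*hag*), the main filament protein of the flagellum, was 6.76-fold lower at pH 4.0 (interval 6.36 to 7.20), with 147 and 142 CPM against 983 and 972 in the control. The flagellar motility and chemotaxis list did not follow it, with 12 of 49 members higher and 9 lower. The general stress sigma factor *sigB* was 11.6-fold higher (10.1 to 13.1), at 304 and 305 CPM against 27.4 and 25.2. The biofilm amyloid gene *tasA* was 26.6-fold higher (15.95 to 50.3), whereas *spo0A*, which encodes the regulator that starts sporulation, was 4.45-fold lower (4.00 to 4.93). L-lactate dehydrogenase (*ldh*) stood at 175 and 17.4 CPM in the pH 4.0 libraries, which differ from each other, against 930 and 931 CPM in the control. Of the counts of these genes, 12.9% of those of *hag* and 13.7% of those of *ldh* came from closely matching rows, against 83.4% for *sigB*, 98.9% for *tasA* and 79.9% for *spo0A*.

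By the size rule, 1183 of 8769 genes were higher and 1450 lower at pH 4.0 than in the control, 854 and 558 of them among the 3126 genes found in the reference. The excess of lower genes was thus absent among reference genes. Of those 2633 genes, 1609 held over 50% of their counts in closely matching rows, and the remaining genes were 139 higher and 885 lower. At pH 4.0, 195 genes had 0 counts against at least 100 in the control, and 120 showed the opposite. The largest differences were all genes at 0 in a group. *yvfV* (lactate utilization), *yqkB* (an iron-sulfur cluster protein), *mtlF* (mannitol uptake), *yjbP* and the cell division gene *divIC* were at least 2065-fold, 1831-fold, 1827-fold, 1613-fold and 1567-fold higher at pH 4.0. *rghRB* (a transcriptional regulator), the spore coat gene *cotZ*, *yorW*, *yhjR* (a ferritin family protein) and *yngG* were at least 1402-fold, 878-fold, 841-fold, 831-fold and 748-fold lower. Between 99.6% and 100% of the counts of these genes came from closely matching rows. The closeness of replicates in those rows is no replicate check of these folds, and their levels had a Spearman rho of only 0.17 to 0.21 between groups.

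Among 44 measured members of the SigB general stress list, 19 were higher at pH 4.0, 8 lower and 17 neither, or 13 higher and 9 lower under upper quartile scaling. The base for this list and those below is the 3126 reference genes, of which 854 were higher and 558 lower at pH 4.0. The sugar nucleotide gene *gtaB* was 10.03-fold lower (9.35 to 10.8), with 1.9% of its counts in closely matching rows, and the catalase gene *katE* was at 0 counts and at least 247-fold lower. Over 50% of the counts came from closely matching rows in 37 of the 44 members. The base for this share, here and in the lists below, is 2320 of 3126 reference genes. No higher SigB member lay outside these 37, where 139 of the 1183 higher genes over all 8769 held 50% or less of their counts in closely matching rows. edgeR called 26 members higher and 10 lower over all genes tested, and the same numbers adjusted over the list alone. The list's median log2 ratio of 0.75 (floor-based 0.76) lay at percentile 89.7 of random lists.

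The biofilm matrix list had 11 of 25 members higher, 5 lower and 9 neither, or 10 higher and 5 lower under upper quartile scaling. *slrR*, a regulator of matrix genes, was at least 1076-fold higher, and *epsN* of the exopolysaccharide operon was 93.5-fold higher (39.5 to 237). Of the 25 members, 23 held over 50% of their counts in closely matching rows. edgeR called 14 higher and 6 lower over all genes tested and 14 and 7 adjusted over the list alone, and the median of 0.92 (floor-based 0.93) lay at percentile 89.8.

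The list of secondary metabolites and antimicrobial peptides had 15 of 46 members higher, 3 lower and 28 neither (7 higher and 4 lower under upper quartile scaling), with a median of 0.63 at percentile 99.0, floor-based 0.77. *bacC* of the bacilysin pathway was 3.18-fold higher (3.07 to 3.29). In the bacillaene cluster, *pksB* was at least 874-fold higher and *pksS* 5.65-fold higher (4.48 to 7.27), whereas *pksH* was 215-fold lower (44.2 to 1333). In 35 of the 46 members over 50% of the counts came from closely matching rows. edgeR called 21 higher and 4 lower, both over all genes tested and adjusted over the list alone. camera called this list with an adjusted p = 0.0171 at the preset correlation, and the call was lost at adjusted p = 0.964 with an estimated correlation.

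The purine synthesis list had 4 of 21 members higher, 0 lower and 17 neither, or 3 higher and 0 lower under upper quartile scaling. *xpt* was 4.06-fold higher (3.76 to 4.43), *purQ* 3.24-fold (2.97 to 3.50) and *guaC* 2.92-fold (2.77 to 3.11), while *purD* did not pass the size rule at 767 and 749 CPM against 418 and 415. The median log2 ratio of 0.52 (floor-based 0.55) lay at percentile 84.3 of random lists, inside the middle 95%. In 7 of the 21 members over 50% of the counts came from closely matching rows. edgeR called 14 higher and 2 lower over all genes tested and 15 and 2 adjusted over the list alone. camera gave an adjusted p = 0.0247 at the preset correlation and an adjusted p = 0.964 with an estimated correlation, and without pH 4.0 replicate 1 the preset value was 0.0555.

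Lists whose median lay low among random lists were glutamate and nitrogen metabolism (median log2 ratio −0.48, floor-based −0.48, percentile 0.5), sulfur metabolism (−0.06, floor-based −0.05, percentile 1.5) and mother cell and spore coat (−0.39, floor-based −0.52, percentile 2.3). camera at the preset correlation called none of them, with adjusted p of 0.943, 0.819 and 0.604. Percentiles rank these medians among reference genes, of which 854 were higher and 558 lower. The sulfur median of −0.06 is thus close to no change against the control. The 18 glutamate and nitrogen genes had 3 members higher and 3 lower (3 and 5 under upper quartile scaling). Its members with the smallest edgeR p were nitrogen regulators that lay higher, *tnrA* by 24.4-fold (21.6 to 27.4) and *glnR* by 224-fold (120 to 461). In sulfur, cysteine and methionine metabolism, 4 of 36 members were higher and 11 lower (2 and 13 under that scaling), with the methionine transporter gene *metN* 8.12-fold higher (7.49 to 8.88) and the sulfate reduction gene *cysH* 33.6-fold lower (26.2 to 44.1). Of 47 mother cell and spore coat genes, 11 were higher and 13 lower (7 and 17 under that scaling), among them *spoIIM* at 20.5-fold higher (17.7 to 24.1) and the coat protease gene *yabG* at 76.7-fold lower (43.4 to 168). edgeR called 6 higher and 6 lower, 12 and 14, and 13 and 20 in these lists over all genes tested, and 6 and 6, 12 and 15, and 13 and 20 adjusted over the list alone. Between 90% and 98.3% of the counts of the members named here came from closely matching rows.

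ATP synthase had 2 of 9 members higher and 1 lower at pH 4.0 (2 and 2 under upper quartile scaling), with *atpF* 491-fold higher (282 to 1085) and *atpC* 11.9-fold lower (9.63 to 14.7), and a median at percentile 45.3. Ribosomal proteins had 9 of 50 members higher and 12 lower (5 and 15 under that scaling), with *rplI* 18.9-fold (16.2 to 22.0) and *rplF* 6.33-fold higher (5.89 to 6.83), and a median at percentile 6.1. Of the counts of *atpF* and *atpC*, 99.4% and 91.9% came from closely matching rows, and of those of *rplI* and *rplF* 91.8% and 85.3%. edgeR called 3 and 1 of the ATP synthase list and 13 and 18 of the ribosomal protein list higher and lower, both over all genes tested and adjusted over the list alone. Of the remaining fixed genes, *alsD*, which makes acetoin from acetolactate, was 2.51-fold higher (2.36 to 2.71), a call lost under upper quartile scaling (log2 ratio 0.89 against 1.32), and the Clp ATPase gene *clpE* 2.48-fold lower (2.19 to 2.80). The chaperone genes *dnaK* and *groEL* were at 1.16-fold (1.13 to 1.20) and 1.19-fold (1.16 to 1.22) of the control, cytochrome bd oxidase (*cydA*) at 1.30-fold (1.25 to 1.37), urease (*ureC*) at 1.19-fold (1.16 to 1.23) and acetolactate synthase (*alsS*) at 1.77-fold (1.60 to 1.98), none of which passed the size rule. The surfactin synthetase gene *srfAA* stood at 64.3 and 144 CPM at pH 4.0 against 103 and 109 in the control.

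edgeR's quasi-likelihood test called 2371 genes higher and 2662 lower at pH 4.0 than in the control at the adjusted threshold of 0.05, and this, like the counts per list and the p-values of camera and fry, measures only the spread between library files that are not independent. Under upper quartile scaling, which shifted log2 ratios by −0.44, the share called higher was 27.6% against 47.1% with TMM, and that of the size rule 30.2% against 44.9%.

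**Figure D2:**
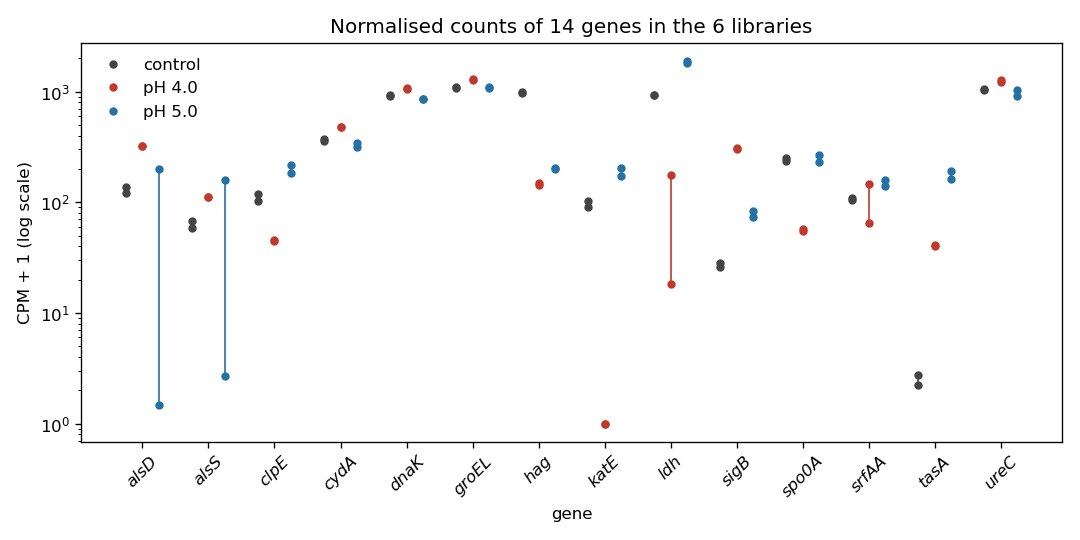
CPM + 1 on a log axis (vertical) for the 14 measured genes fixed in advance (horizontal), with 1 point per library, coloured by group, and a line joining the libraries of a group. *hag* lies at 983 and 972 CPM in the control and at 147 and 142 CPM at pH 4.0, and the libraries stand far apart for *ldh* at pH 4.0 (175 and 17.4 CPM) and for *alsD* at pH 5.0 (199.5 and 0.475 CPM).

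The next comparison set overnight growth at pH 5.0 against the control. Flagellin (*hag*) was 4.89-fold lower at pH 5.0 (4.65 to 5.14), at 203 and 197 CPM. The flagellar motility and chemotaxis list did not follow it, with 11 of 49 members higher and 4 lower. The gene *tasA* was 118-fold higher (70.9 to 219), at 160 and 191 CPM against 1.75 and 1.24, and *sigB* was 2.93-fold higher (2.51 to 3.36), a call lost under upper quartile scaling (log2 ratio 1.03 against 1.51). The ATP synthase gene *atpA* was 2.81-fold lower (2.72 to 2.88), and the ribosomal protein gene *rpsL* was 73.7-fold lower (71.1 to 76.6). Closely matching rows held 12.9% of the counts of *hag*, 98.9% of those of *tasA*, 83.4% of those of *sigB* and 99.8% of those of *rpsL*. In contrast *spo0A* was at 1.02-fold of the control (0.954 to 1.07) and *ldh* at 1.99-fold (1.94 to 2.04), and neither passed the size rule.

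By the size rule, 1071 of 8769 genes were higher and 994 lower at pH 5.0 than in the control, 825 and 337 of them among reference genes. Of those 2065 genes, 1335 held over 50% of their counts in closely matching rows, and the remaining genes were 65 higher and 665 lower. At pH 5.0, 97 genes had 0 counts against at least 100 in the control, and 166 showed the opposite. The largest differences again involved a group at 0. The germination gene *gerT*, *yyaT* (an acetyltransferase family gene), *yezC* (an AsnC family regulator), *ysnB* and *yviE* were at least 1556-fold, 1536-fold, 1283-fold, 1248-fold and 1190-fold higher. *yhjR*, *yuzD*, *yneI*, the urease subunit gene *ureB* and *yqaN* were at least 989-fold, 817-fold, 736-fold, 710-fold and 699-fold lower. Between 99.8% and 100% of the counts of these genes came from closely matching rows, whose closeness is no replicate check of these folds.

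ATP synthase had 0 of 9 members higher at pH 5.0, 4 lower and 5 neither (0 and 5 under upper quartile scaling), with a median log2 ratio of −1.44 (floor-based −1.37) at percentile 0.1 of random lists. Besides *atpA*, with 55.9% of its counts in closely matching rows, *atpH* was 4.53-fold lower (3.38 to 6.36). camera at the preset correlation gave this list an adjusted p = 0.149, past no threshold. The ribosomal protein list had 11 of 50 members higher and 9 lower (8 and 14 under upper quartile scaling) with a median of −0.20 (floor-based −0.21), also at percentile 0.1, and its member *rpsK* was 19.4-fold higher (17.0 to 21.9). Of these 50 members, 27 held over 50% of their counts in closely matching rows, against 2320 of 3126 reference genes. The random lists did not match that share, so the percentile alone does not show a fall. The anaerobic and nitrate respiration list had 1 of 12 members higher and 3 lower, as under upper quartile scaling (median −0.33, floor-based −0.38, percentile 1.9), with the nitrate reductase assembly gene *narJ* 493-fold lower (99.3 to 2977) and *nasF* 5.58-fold higher (4.82 to 6.47). Translation factors and RNA polymerase had 1 of 22 members higher and 4 lower, or 1 and 8 under that scaling (median −0.15, floor-based −0.27, percentile 2.2). edgeR called 1 and 4, 14 and 17, 2 and 3, and 5 and 9 members of these lists higher and lower over all genes tested. The corresponding counts adjusted over the list alone were 1 and 4, 15 and 18, 2 and 3, and 5 and 9. For the ribosomal, anaerobic and translation lists, camera at the preset correlation gave adjusted p of 0.787, 0.596 and 0.259, also past no threshold.

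The list of secondary metabolites and antimicrobial peptides had 12 of 46 members higher at pH 5.0, 2 lower and 32 neither (9 higher and 3 lower under upper quartile scaling), with a median of 0.62 (floor-based 0.58) at percentile 95, inside the middle 95%. *pksB* was at least 363-fold and *pksS* 17.0-fold higher (13.6 to 21.4), the subtilosin cluster gene *albC* was 3.64-fold higher (3.35 to 3.96), and *pksH* was at least 128-fold lower. edgeR called 20 higher and 2 lower, both over all genes tested and adjusted over the list alone. camera called the list at an adjusted p = 0.0178 with the preset correlation and not with an estimated correlation, at adjusted p = 0.93. The preset value was 0.0835 without control replicate 1 and 0.124 without pH 5.0 replicate 2.

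The biofilm matrix list had 12 of 25 members higher and 2 lower (10 and 5 under upper quartile scaling), with *slrR* at least 852-fold higher and *epsN* 250-fold higher (106 to 629). The SigB list had 11 of 44 members higher and 6 lower (8 and 6 under that scaling, with a median of 0.00), with *yxbG* 31.2-fold higher (22.2 to 44.3) and *gtaB* 2.70-fold lower (2.60 to 2.82). Of the 3126 reference genes, 825 were higher and 337 lower at pH 5.0, so the SigB share higher lay near that base. The medians of the biofilm and SigB lists, 1.15 (floor-based 1.25) and 0.47 (floor-based 0.48), lay at percentiles 95.2 and 61.2. No higher member of either list held 50% or less of its counts in closely matching rows, where 65 of the 1071 higher genes over all 8769 did. edgeR called 15 and 5 biofilm genes and 22 and 7 SigB genes higher and lower over all genes tested, and 15 and 6, and 24 and 7, adjusted over the list alone. Of the fixed genes, *katE* was at 1.95-fold of the control (1.79 to 2.11), *clpE* at 1.80-fold (1.66 to 1.94) and *srfAA* at 1.41-fold (1.29 to 1.52). *dnaK*, *groEL*, *cydA* and *ureC* were at 0.930-fold (0.901 to 0.958), 1.01-fold (0.981 to 1.04), 0.897-fold (0.853 to 0.940) and 0.929-fold (0.906 to 0.959), and none of these genes passed the size rule. The pH 5.0 libraries gave 199.5 and 0.475 CPM for *alsD*, against 120 and 136 in the control, and 157 and 1.66 CPM for *alsS*, against 58.0 and 66.4, so no direction is given for these genes.

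edgeR called 1936 genes higher and 2036 lower at pH 5.0 than in the control at the adjusted threshold of 0.05, with the same limit on what its spread measures. Under upper quartile scaling, which shifted log2 ratios by −0.49, the share called higher was 25.2% against 48.7% with TMM, and that of the size rule 34.6% against 51.9%.

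**Figure D3:**
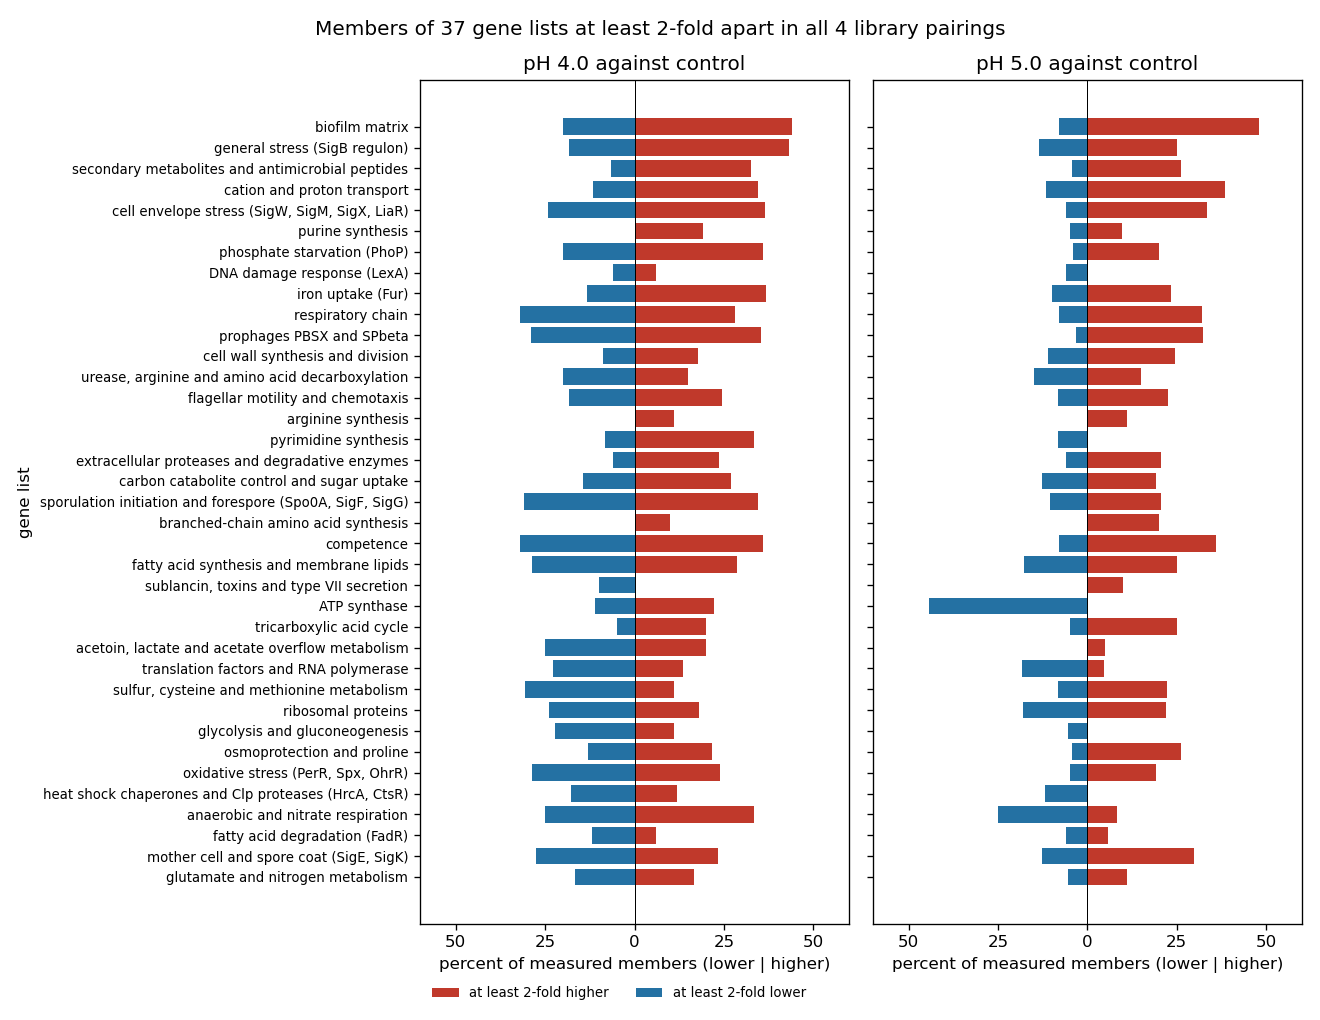
Percent of measured members of each of 37 gene lists that were at least 2-fold higher (right of 0) or lower (left of 0) in all 4 library pairings, for pH 4.0 against control and pH 5.0 against control. ATP synthase has 4 of 9 members lower and 0 higher at pH 5.0, and the biofilm matrix list has 11 and 12 of 25 members higher at pH 4.0 and pH 5.0, or 10 and 10 under upper quartile scaling.

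The acidic cultures were also compared with each other. At pH 4.0, *ldh* stood at 175 and 17.4 CPM against 1884 and 1816 at pH 5.0. *spo0A* was 4.52-fold lower at pH 4.0 than at pH 5.0 (4.05 to 4.99), *tasA* 4.42-fold lower (3.88 to 4.98) and *clpE* 4.46-fold lower (3.94 to 4.99), whereas *sigB* was 3.95-fold higher (3.65 to 4.32). *katE* had 0 counts at pH 4.0 and was at least 482-fold lower. *atpA* was 4.78-fold higher at pH 4.0 (4.64 to 4.90) and *atpF* 431-fold higher (237 to 803).

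By the size rule, 893 of 8769 genes were higher and 1155 lower at pH 4.0 than at pH 5.0, 530 and 677 of them among reference genes. Of those 2048 genes, 1402 held over 50% of their counts in closely matching rows, and the remaining genes were 252 higher and 394 lower. At pH 4.0, 219 genes had 0 counts against at least 100 at pH 5.0, and 51 showed the opposite. The flavodoxin family gene *fldP*, *yloU*, *yuzD*, *yozO* and *ypuF* were at least 1860-fold, 1819-fold, 1731-fold, 1369-fold and 1258-fold higher at pH 4.0. *ytkA*, *ysnB*, *ypiP*, *yhaI* and the PBSX prophage gene *xkdU* were at least 1168-fold, 1004-fold, 968-fold, 922-fold and 886-fold lower. Between 99.4% and 100% of the counts of these genes came from closely matching rows, whose closeness is no replicate check of these folds.

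ATP synthase had 4 of 9 members higher at pH 4.0 than at pH 5.0, 1 lower and 4 neither, with a median log2 ratio of 1.65 (floor-based 1.59) at percentile 99.9. Acetoin, lactate and acetate overflow metabolism had 2 of 20 members higher and 5 lower (median −0.39, floor-based −0.48, percentile 2.2), with the acetoin utilization gene *acuB* 103-fold lower (42.8 to 256) and the butanediol dehydrogenase gene *bdhA* 11.5-fold lower (9.96 to 13.3). Of the counts of *bdhA*, 32.4% came from closely matching rows. The biofilm matrix list had 5 of 25 members higher and 9 lower (5 and 10 with library totals alone), with a median of 0.01 (floor-based 0.02, percentile 61.2) where camera pointed down, and with *epsF* at least 273-fold lower and *epsB* 5.61-fold lower (5.01 to 6.19). The SigB list had 8 of 44 members higher and 5 lower (7 and 6 with library totals alone), with *gtaB* 3.71-fold lower (3.44 to 4.03) and a median of 0.19 (floor-based 0.23) at percentile 76.0. The base for these lists is 530 higher and 677 lower of the 3126 reference genes. edgeR called 5 and 1, 6 and 8, 7 and 11, and 17 and 11 members of these lists higher and lower over all genes tested. Adjusted over the list alone, the counts were 5 and 1, 6 and 8, 8 and 11, and 17 and 11. camera gave ATP synthase an adjusted p = 0.363 at the preset correlation and an adjusted p = 0.992 with an estimated correlation, past no threshold. For the overflow metabolism list camera gave an adjusted p = 0.951 at the preset correlation.

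Of the other fixed genes, *hag* at pH 4.0 was at 0.724-fold of its pH 5.0 level (0.671 to 0.779), *dnaK* at 1.25-fold (1.21 to 1.29), *groEL* at 1.18-fold (1.15 to 1.21), *cydA* at 1.45-fold (1.39 to 1.53) and *ureC* at 1.28-fold (1.24 to 1.32). None of these differences passed the size rule. *srfAA* stood at 64.3 and 144 CPM at pH 4.0, libraries that differ from each other, against 140 and 158 at pH 5.0. *alsD* and *alsS* gave 320 and 323 CPM and 110 and 110 CPM at pH 4.0, to be set against pH 5.0 libraries that differ from each other. edgeR called 2209 genes higher and 2294 lower at pH 4.0 than at pH 5.0, with the same limit on what its spread measures.

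Both acidic groups were compared with the same control libraries, and these cannot be split between the comparisons. By the size rule, 570 genes were higher and 534 lower than the control in both groups, and 164 went in opposite directions. Independent lists of these sizes would share 144 and 164 genes, and simulated unchanged groups against the same control libraries shared 1.45 and 39 on average over 20 draws. The simulated lists were far smaller, with means of 13.75 and 14.05 genes higher and 85 and 84 lower at pH 4.0 and pH 5.0. Their shared counts therefore cannot be set directly against the observed ones. edgeR called 1162 genes higher and 1362 lower in both, with 567 opposite, against 523 and 618 for independent lists and 0 and 0.5 in the simulation. Independent lists of the sizes edgeR gave in the simulation would share at most 0.003 genes. Those lists were near empty, so 0 and 0.5 do not measure what the shared control adds. Across the 8769 genes, which are not independent replicates, the log2 ratios had a Pearson r of 0.516 against a mean of 0.558 in the simulation (0.514 to 0.600), a Spearman rho of 0.50 against 0.465 (0.449 to 0.482), and a covariance of 1.72 against 0.149.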

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

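The tests with reference genes only, closely matching or other rows only, a 4-fold limit or random-list percentiles, the size rule itself, and its calls of genes and list members under each scaling, were chosen after the results were seen, and the others before. For pH 4.0 against control, pH 5.0 against control and pH 4.0 against pH 5.0, edgeR called 5033, 3972 and 4503 genes. Of their recomputed counts 48 lay within 1.5 times and 12 did not. With rows as deposited, 35211 features entered the fit and the counts were 16024, 11906 and 14028. A 2-fold limit beside the adjusted p left 3237, 2480 and 2656, reference genes only gave 2139, 2085 and 2036, and closely matching rows only gave 2527, 2528 and 2555. The number of features or the limit differed in each of these settings. The counts did not shrink in proportion, since 3126 reference genes and 3395 genes with closely matching rows entered those fits, against 8769. The cause was not tested. Under the size rule, a 4-fold limit gave 1248, 960 and 909 genes. The other rows alone gave 1528, 1082 and 1061, of which 15.8%, 13.4% and 44.7% were higher against 44.9%, 51.9% and 43.6%, and the cause was not tested. With each library left out in turn, edgeR called 4281 to 5054, 3243 to 3999 and 3614 to 4369 genes, and the size rule 2632 to 3015, 2060 to 2378 and 2043 to 2429.

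Upper quartile scaling shifted log2 ratios against the control by −0.44 at pH 4.0 and −0.49 at pH 5.0 relative to TMM, and ended the size-rule calls of *alsD* at pH 4.0 (0.89 against 1.32) and *sigB* at pH 5.0 (1.03 against 1.51), the only calls of named genes lost among the 3 other scalings. It turned the sign of *dnaK*, *groEL*, *ureC* and *cydA* at pH 4.0 (to −0.22, −0.19, −0.18 and −0.05) and of *groEL*, *spo0A* and *alsS* at pH 5.0 (to −0.47, −0.47 and −0.04), none of them called, and RLE turned *groEL* and *spo0A* at pH 5.0 (to −0.02 and −0.01). Library totals alone shifted pH 4.0 against pH 5.0 by −0.12, with 40.1% of called genes higher against 49.1%.

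camera called 2, 1 and 0 lists in the 3 comparisons, with 9, 11 and 3 at an unadjusted p under the threshold. With an estimated correlation it called 0, 0 and 0, with 0 unadjusted in each. fry, which does not compare a list with other genes, called 27, 27 and 25, and RLE scaling gave 3 at pH 5.0. The percentiles put 4, 4 and 2 lists outside the middle 95%. With each library left out, the lone library being assumed to vary like the others, 1 to 3 lists were called at pH 4.0, the 1 without pH 4.0 replicate 1. At pH 5.0 the range was 0 to 7, with 0 without control replicate 1 or pH 5.0 replicate 2, 7 without control replicate 2 and 6 without pH 5.0 replicate 1. The cause was not tested.

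Among named genes, 866 recomputed values kept their direction and side of the threshold, 21 came past it and 10 no longer passed. Another 8 turned sign and 4 came to 0 without passing the threshold, among *groEL*, *spo0A*, *srfAA* and *alsS*, and 3 reversed. *alsD* at pH 5.0 against control ranged from −8.03 (log2, without pH 5.0 replicate 1) to 0.64 (without pH 5.0 replicate 2) and *alsS* from −5.21 to 1.34 under the same settings. *alsS* at pH 4.0 against pH 5.0 ranged from −0.51 without pH 5.0 replicate 2 to 6.04 without pH 5.0 replicate 1. The pH 5.0 libraries stand apart for these genes. With the replicate number as a block, edgeR called 4809, 3810 and 4302 genes, no list call changed, and *alsS* at pH 5.0 against control was −0.50. Deviations of equally numbered libraries had a Pearson r of −0.036 (control and pH 4.0), 0.031 (control and pH 5.0) and 0.028 (pH 4.0 and pH 5.0) and a Spearman rho of 0.061, 0.259 and 0.106 across genes, which leaves open whether equal numbers share a day or culture. The labels do not pair them. Removing stable RNA was not run, since 0 rows name such a product. Depth limits genes at 0 counts to bounds set by 3 counts.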

Other observations

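The genes and patterns here, and which lists are described, were picked after their values were seen. The edgeR and camera tests of the lists, the test of single-library gaps on neighbouring folds and that of the neighbours of gap genes were chosen beforehand, and the other tests after the results were seen. The 10 genes with the highest mean CPM in the control were picked for being high there, so their ratios lean toward the control. Elongation factor Tu (*tufA*) stood at 27318 CPM in the control, 8.88 times its level at pH 4.0 and 8.88 times that at pH 5.0. The ribosomal protein genes *rplK*, *rplC*, *rpsD* and *rpsL* stood at 7.15, 4.25, 3.85 and 10.1 times their pH 4.0 level and 5.58, 2.12, 4.12 and 73.7 times their pH 5.0 level, and elongation factor G (*fusA*) at 3.92 and 5.09 times. The ribosomal protein gene *rplP* gave 15639 and 35.6 CPM in the control libraries and *fbaA*, of glycolysis, 1039 and 26.7 CPM in the pH 5.0 libraries. Over all 50 measured ribosomal protein genes, 9 were higher, 12 lower and 29 neither at pH 4.0 (5 higher and 15 lower under upper quartile scaling), and 11, 9 and 30 at pH 5.0 (8 higher and 14 lower). Of the counts of the highest genes named so far 77.8% to 99.9% came from closely matching rows. In *smpB*, whose product acts with tmRNA to free stalled ribosomes, 2.9% did, and it stood at 29.2 times its pH 4.0 level and 3.31 times its pH 5.0 level, and in *ywhH* 1.9% did, with ratios of 274 and 7.82.

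Of 25 competence genes, which serve DNA uptake, 9 were higher and 8 lower than the control at pH 4.0 (6 and 9 under upper quartile scaling), and 9 and 2 (9 and 3) at pH 5.0. edgeR called 11 and 9, and 14 and 2, over all genes tested and 12 and 9, and 14 and 2, adjusted over the list alone. Of 49 genes of flagellar motility and chemotaxis, 12 were higher and 9 lower at pH 4.0 (9 and 11 under that scaling), and 11 and 4 (10 and 7) at pH 5.0, with edgeR counts of 22 and 14, and 22 and 10, over all genes tested and 23 and 14, and 23 and 11, adjusted over the list alone. Of 25 genes of the respiratory chain, 7 were higher and 8 lower at pH 4.0 (5 and 8 under that scaling), and 8 and 2 (6 and 5) at pH 5.0, with edgeR counts of 12 and 8, and 12 and 5, over all genes tested and 12 and 9, and 12 and 6, adjusted over the list alone. The base for these lists is the 3126 reference genes, of which 854 were higher and 558 lower at pH 4.0, and 825 and 337 at pH 5.0. camera called none of these lists, with adjusted p of 0.0562 or more. These edgeR counts and p-values rest on library files that are not independent.

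Part of the table's counts lay closer between replicates than counting noise. Separate libraries for those counts are argued against by a median squared difference of at most 0.037 times counting noise in any group, and the sharing out of ambiguous reads by the counting tool by 0.035 among whole-number values. A whole library deposited under both names is argued against by a chi-square per degree of freedom of at least 22.8 over all genes. No biological explanation was tested, and what made these counts stays open.

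Log2 folds of neighbouring genes, many of which share operons in bacteria, were nearly unrelated, with r of −0.015 and 0.028 over 2214 pairs. Low counts as the whole cause are argued against by an r of at most 0.054 among genes with a mean of at least 500 counts, and single-library gaps by at most 0.022 without them. A candidate explanation that stays open is that counts in the closely matching rows do not follow the genes they are named for, where levels of neighbours correlated at no more than 0.09 in any group. The other rows gave no more than 0.087, so this value does not set the closely matching rows apart. Gene names scattered at random over the gene order are argued against by the pH 5.0 pair, for the genes it covers. There all 55 genes of at least 500 counts and 8-fold or more apart lay in 1 window of 250 genes, against at most 13 in 1000 random draws. Names exchanged among genes of such a stretch would leave them gathered too, so this test cannot decide on those. No biological explanation was tested.

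Beside the genes near 0 in a single library, genes with at least 500 counts that lay 8-fold or more apart between replicates gathered along the gene order, with 24 of 89 in a window of 250 genes in the control pair (random highest 18) and 44 of 150 in the pH 4.0 pair (random highest 24). Reads moved to other rows of the same gene name are argued against, since a median share of at most 0.007 was found there. In that median, a gene without other rows counts as none found. Movement to rows of another gene name was not tested. For loss of a stretch of the chromosome, 17.9% to 58.3% of neighbours of gap genes were also 8-fold lower, against 1.1% to 5.1% of all genes, which met neither bound set beforehand. In the fullest window of the control pair, 24 of 147 genes with at least 500 counts were 8-fold or more apart. Of these, 91.7% were lower in replicate 1, as loss in 1 library could give. Loss of that whole window is argued against, since most of its genes were not 8-fold apart. Loss of shorter stretches within it stays undecided. Among the genes 8-fold apart in the pH 4.0 pair's fullest window, 72.7% were lower in the same library, which leaves loss undecided. The corresponding 52.7% in the pH 5.0 pair argues against loss in 1 library alone. No biological explanation was tested.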
